A study of Homo sapiens with 8 samples.

How the data were processed

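RNA-seq libraries of C4-2 prostate cancer cells, 4 treated with 1 µM DTHIB for 48 h and 4 with DMSO, were compared. Samples were grouped by the treatment in their labels. Per the labels' protocols, poly(A) RNA was enriched from total RNA before library construction.

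Per the submitters' processing notes, Trimmomatic 0.36.5, HISAT2 2.1.0, StringTie 1.3.4, featureCounts 1.6.3 and DESeq2 2.11.40.2 were used with the build GRCh38; their order and settings, the gene annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. By its name, the signal that the authors deposited, 1 per gene and library, was a DESeq2-normalized count. Such a count is reads divided by a size factor of the library. The authors also deposited a DESeq2 result with the mean normalized count (a signal), the log2 fold change with its standard error, the Wald score, the p-value and the adjusted p-value per gene; the sign of the deposited log2 fold change matched DTHIB minus DMSO in 100% of genes above 10 reads. Whether the alignment included alternate sequences is not given in the sources used here, so genes with copies there were marked with GENCODE release 29, which lists 2050 symbols with transcripts outside the primary assembly.

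In each column every value was a whole multiple of 1 step, 100% of values within a tolerance of 0.01, so whole reads were recovered and summed to library totals of 27229291 to 30926053. At this depth the tested genes have a mean of at least 10 normalized counts, and genes near that limit carry the largest counting error. Gene identifiers were matched to symbols, 41967 of 58884, and to GENCODE release 29 positions on GRCh38, 58611 of 58884. All 8 columns of per-sample values were used.

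Values were analysed as log2(normalized count + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an expression trend), two-sided, over genes with a mean normalized count of at least 10 in the 8 libraries, without covariates. Fold changes are on this log2(value + 1) scale, which understates the change of low genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were said to have changed, risen or fallen. Adjusted p-values in the text are limma's unless another tool is named. A library of each group was left out in turn. Replicates were compared before averaging: a chi-square statistic per gene of 2.39 to 5.21 within groups, and of 51.7 or more between groups, showed no pair of libraries that agreed within sampling noise.

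Gene lists were tested with camera of limma on the same log2 values, with a preset inter-gene correlation of 0.01, a variance trend with expression, and Benjamini-Hochberg adjustment over the 26 of 30 lists with at least 5 tested members; 13 lists passed, 2 higher and 11 lower. The variance trend in camera was not part of the design fixed before the data were examined: a first run without it, adjusted over more lists, gave the same calls with the preset correlation but did not pass the ATF4 list with an estimated correlation, and both settings are therefore reported. With an estimated correlation 1 list passed with the variance trend (ATF4 targets) and none without it. The test fry, which asks whether a list moves one way on balance and does not compare it with other genes, passed 21 lists. The lists, the design, the alternatives and the rule for named genes were fixed before the data were examined. A further 6 lists (cytosolic and mitochondrial aminoacyl-tRNA synthetases, translation factors with 5' terminal oligopyrimidine motifs, snoRNA host RNAs, mitochondrial ribosomal proteins, spliceosomal proteins) were chosen after seeing the data.

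The named genes are a fixed set of heat shock genes with HSF1, HSF2 and KLK3, and 1 more gene that is not reported here; the 12 largest rises and 12 largest falls among changed genes with a mean normalized count of at least 100, a symbol and no overlap between groups; and in each list up to 4 members with the smallest adjusted p. Other genes named were chosen after their values were seen.

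Alternatives were pseudocounts of 0.5 and 5, no filter or a mean of at least 50, TMM rescaling, quantile normalization, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, each library left out, and an estimated correlation in camera. Added after seeing the data were fits without genes that have copies outside the primary assembly, with a trend with transcript length and GC content removed (splines with 4 degrees of freedom), with libraries thinned to 27229291 reads, and camera without a variance trend. On recovered reads edgeR called 11130 genes and DESeq2 10283.

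The tests were tried on simulated counts of the 17194 genes with the real means, library sizes and group sizes, with 50 genes changed at each fold. For DTHIB against DMSO, limma recovered 56% of genes changed 1.25-fold, 76% at 1.5-fold, 86% at 2-fold and 100% at 4-fold. Of its calls, 4.35% were false. Few genes were changed in the simulation, while 64.6% were called in the data, so these rates need not hold here. Camera recovered a list of 40 genes changed 1.25-fold and called 0 of 20 unchanged lists. Simulated genes were drawn independently of each other, so this could not show false calls of lists with correlated members. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and drew the plots.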

Results

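Poly(A)-selected RNA from C4-2 cells, a castration-resistant human prostate cancer line derived from LNCaP, was sequenced after 48 h with 1 µM DTHIB or with its solvent DMSO. DTHIB is described in the labels as a direct inhibitor of HSF1, the transcription factor that activates heat shock genes. There were 4 libraries in each of the 2 groups, and the comparison asks how the transcriptome of these cells differed under the compound. The DMSO libraries held 29499458 to 30926053 counted reads and the DTHIB libraries 27229291 to 29159387. Of the 58884 genes in the table, 17194 had a mean normalized count of at least 10 and were tested. Replicates of a group correlated with Pearson coefficients of 0.993 to 0.994 across genes on the log2 scale, and libraries of different groups with 0.973 to 0.981; genes are not independent replicates.

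In DTHIB-treated cells 28 of 35 tested heat shock genes and 99 of 100 replication, mitosis and recombination genes fell, while all 35 ATF4 target genes and 71 of 74 cytosolic ribosomal protein genes rose; 3 heat shock genes rose. As lists, only the ATF4 targets passed with an estimated correlation (adjusted p = 0.032, or 0.0605 without a variance trend), against adjusted p = 0.33 for heat shock genes and 0.283 for the replication, mitosis, recombination and ribosomal protein lists. The ribonucleotide reductase subunit RRM2 fell from 11421 ± 714 to 2236 ± 87.9 normalized counts (SD, n = 4 libraries per group in all such values). The chaperone HSP90AA1 fell from 136442 ± 3163 to 92750 ± 2593. The cystine transporter SLC7A11 rose from 2179 ± 122 to 13500 ± 468. In all, 11110 genes changed (64.6% of those tested) by limma with Benjamini-Hochberg adjustment, 5324 higher and 5786 lower in DTHIB. Of these genes 1368 changed at least 2-fold, 618 higher and 750 lower, a number that depended on the filter on low values (2578 with none, 701 with a mean of at least 50). The 4 values of one group lay wholly above those of the other in 9959 genes, 57.9% of those tested, where chance gives 2.86%.

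Of 35 tested heat shock genes, 28 fell and 3 rose, with a median log2 fold change of -0.45. HSPH1, an HSP110 co-chaperone, fell by 0.59 on the log2 scale (SE 0.029), from 21857 ± 653 to 14560 ± 388 normalized counts. The J-domain co-chaperone DNAJB1 fell from 4304 ± 73.4 to 2927 ± 175, the small heat shock protein HSPB1 from 37556 ± 2313 to 24598 ± 1501, and the HSP70 cofactor BAG3 from 3642 ± 18.8 to 2655 ± 103. HSPA8, the constitutive HSP70, had a log2 fold change of -0.33, DNAJA1 of -0.55 and DNAJB4 of -0.85. Clusterin (CLU), a secreted chaperone, fell from 5316 ± 338 to 1962 ± 137. The members that rose were HSPA9, the mitochondrial HSP70 (0.56), DNAJB2 (0.48) and ZFAND2A (0.24). HSP90AB1 had a log2 fold change of -0.10, which passed the test (limma adjusted p = 0.00675) except after removal of a trend with transcript length and GC content (adjusted p = 0.0922). HSF1 itself had 5260 ± 207 normalized counts in DMSO and 4897 ± 70.1 in DTHIB; this fall of 0.10 on the log2 scale (limma adjusted p = 0.00841) was lost under quantile normalization, where it was -0.0031 (adjusted p = 0.933). HSF1 is also among the tested genes with transcripts outside the primary assembly, so its counts may depend on where reads were placed. HSF2 fell from 725 ± 30.0 to 533 ± 36.7. The inducible HSP70 genes HSPA1A and HSPA1B held 6 and 7 reads over all 8 libraries; they are near-identical copies of each other, so no level can be given for them. As a list, the heat shock genes were lower than other genes by camera (adjusted p = 1.9e-07; adjusted p = 0.33 with an estimated correlation). Of 13 subunits of the chaperonin TRiC and of prefoldin, which fold actin and tubulin, 11 fell and 1 (PFDN5) rose, with CCT2 at -0.45 and TCP1 at -0.45 (camera adjusted p = 0.00049; adjusted p = 0.433 with an estimated correlation). Counts adjusted over the list alone were the same, 28 and 3 for the heat shock genes and 11 and 1 for the chaperonin subunits.

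Androgen response genes moved both ways. KLK3, which encodes prostate-specific antigen, rose from 66682 ± 643 to 93753 ± 1168 normalized counts, a log2 fold change of 0.49 (SE 0.027; limma adjusted p = 5.7e-11). The kallikrein KLK4 rose from 4864 ± 78.2 to 10821 ± 617, and PMEPA1 from 9132 ± 393 to 15030 ± 439. FKBP5, an HSP90 co-chaperone, fell from 36040 ± 342 to 23557 ± 655, and NDRG1 from 12886 ± 801 to 6840 ± 182. Of 36 members, 13 rose and 16 fell over all genes, 14 and 16 adjusted over the list alone. Camera did not place the list above or below other genes (adjusted p = 0.81), a test that does not register members moving both ways. Of 11 tested androgen-repressed genes, 3 rose and 4 fell by both adjustments (camera adjusted p = 0.81). IGFBP3, an IGF-binding protein, rose to 3210 ± 729 from 1302 ± 411, and MET, the hepatocyte growth factor receptor, fell by 0.96 on the log2 scale.

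**Figure D1:**
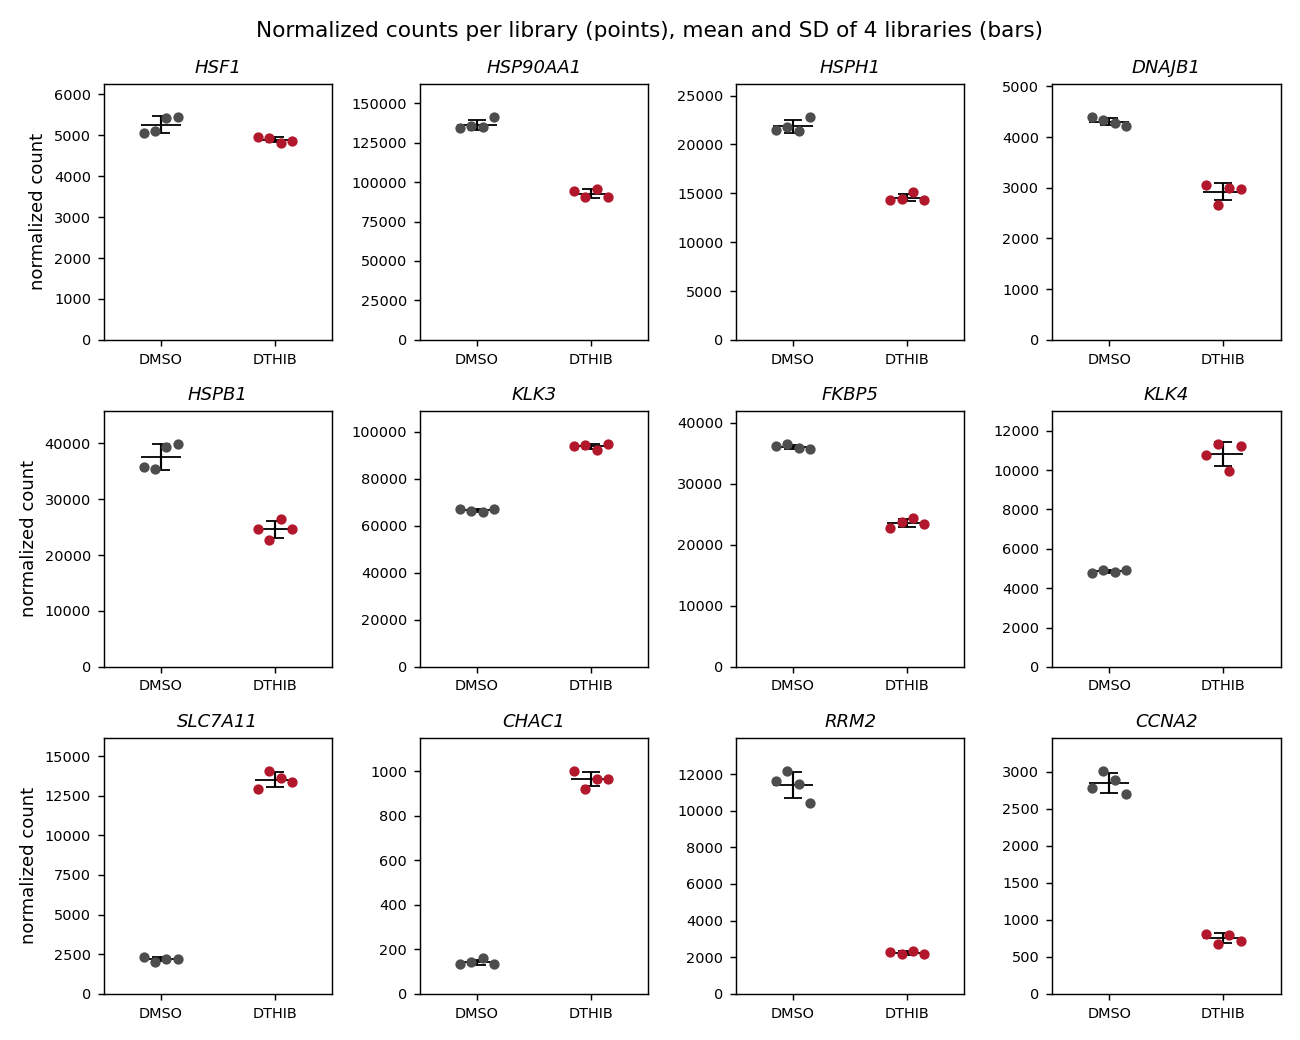
Normalized counts (vertical axis, from 0) of 12 genes in the 4 DMSO and 4 DTHIB libraries; points are libraries, and bars are the mean and SD of each group. HSF1, HSP90AA1, HSPH1, DNAJB1, HSPB1, FKBP5, RRM2 and CCNA2 are lower in all 4 DTHIB libraries than in any DMSO library. KLK3, KLK4, SLC7A11 and CHAC1 are higher in all 4. The fall of HSF1 was lost under quantile normalization.

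Genes of the cell division cycle fell together. Of 40 DNA replication genes, 39 fell and none rose, with a median log2 fold change of -1.39; the remaining gene was POLE (-0.06). The helicase subunit MCM4 fell from 10442 ± 328 to 3401 ± 113 normalized counts, the transcription factor E2F1 from 3464 ± 146 to 990.0 ± 25.3, and the flap endonuclease FEN1 from 4812 ± 145 to 1302 ± 76.1. All 40 mitosis genes fell (median -1.52), among them cyclin A2 (CCNA2), from 2843 ± 136 to 750.0 ± 67.2, and CKS2, ANLN and UBE2C, with log2 fold changes of -1.48, -1.69 and -1.65. All 20 homologous recombination genes fell (median -1.37); BRCA1 had a log2 fold change of -1.65, BRCA2 of -1.66, FANCD2 of -1.35 and the exonuclease EXO1 of -2.06. The counts adjusted over the list alone were 39, 40 and 20. Camera placed these lists below other genes, with adjusted p = 2.6e-27, 4.3e-26 and 7.2e-15, each with adjusted p = 0.283 with an estimated correlation. Of 17 tested replication-dependent histone genes, whose main transcripts lack the poly(A) tail that was selected for, 7 rose and 5 fell by both adjustments (camera adjusted p = 0.49); H2BC11 had a log2 fold change of -1.03, H2AC6 of 0.71, H4C8 of 0.75 and H2BC5 of 0.51.

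All 35 ATF4 target genes rose, also when adjusted over the list alone, with a median log2 fold change of 1.00. ATF4 itself, the transcription factor translated when amino acids are short or the endoplasmic reticulum is stressed, had a log2 fold change of 1.10. CHAC1, a glutathione-degrading enzyme, rose from 143 ± 11.6 to 964 ± 31.9 normalized counts, and cystathionine gamma-lyase (CTH), which makes cysteine, from 514 ± 31.0 to 2196 ± 68.0. The stress cytokine GDF15 rose from 2663 ± 57.9 to 8022 ± 235, STC2 from 2779 ± 26.2 to 7793 ± 91.6, and the seryl-tRNA synthetase SARS1 from 5684 ± 46.2 to 14568 ± 372. The list stood above other genes by camera (adjusted p = 4.3e-26). With an estimated correlation its adjusted p was 0.032 when the variance was allowed to depend on expression, as in the other list tests, and 0.0605 when it was not, so that this call depends on a setting that the fixed design did not specify. Endoplasmic reticulum chaperones and unfolded protein response genes were split, with 12 of 26 higher and 12 lower by both adjustments (camera adjusted p = 0.81): the sensor ERN1 (0.88), SEL1L (0.55) and XBP1 (0.38) rose, and the chaperone HSPA5 (-0.40) and MANF (-0.38) fell.

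Lipid and sugar metabolism genes were mostly lower. Of 24 tested cholesterol synthesis genes, 18 fell and 2 rose; INSIG1, a sterol-regulated retention protein, fell from 9480 ± 451 to 4052 ± 422 normalized counts, and IDI1, FDPS and ACAT2 had log2 fold changes of -0.80, -0.57 and -0.93. The list was lower by camera (adjusted p = 0.00014; adjusted p = 0.335 with an estimated correlation). Of 16 fatty acid synthesis genes, 11 fell and 2 rose, with the desaturases FADS1 at -1.18 and FADS2 at -1.42, the regulator SREBF1 at -0.57 and ACSL3 at -0.50 (camera adjusted p = 0.0018; adjusted p = 0.433 with an estimated correlation). Of 32 tested glycolysis and hypoxia genes, 24 fell and 4 rose (camera adjusted p = 0.00026; adjusted p = 0.433 with an estimated correlation). Lactate dehydrogenase A (LDHA) fell from 26196 ± 565 to 15942 ± 782 and PGAM1 from 10752 ± 199 to 7350 ± 365, while the angiogenic factor VEGFA rose from 2811 ± 171 to 5197 ± 338. Counts adjusted over the list alone were identical for these 3 lists.

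Among cytosolic ribosomal protein transcripts 71 of 74 tested were higher, none was lower, and the median log2 fold change was 0.31. RPL37 rose from 11032 ± 302 to 16422 ± 788, RPS6 from 32376 ± 498 to 43800 ± 523, RPL10 had a log2 fold change of 0.42 and RPS27 of 0.47; FAU (0.00), RPSA (0.05) and RPS9 (-0.10) did not pass the test. The list stood above other genes by camera (adjusted p = 4.4e-21; adjusted p = 0.283 with an estimated correlation). Ribosome biogenesis genes had 8 of 30 members higher and 17 lower (camera adjusted p = 0.31), with NOP58 at -0.64, the nucleolar protein NCL at -0.30, GNL3 at 0.36 and NOB1 at 0.33. Of 37 proteasome subunits, 26 fell and 2 rose, PSMD2 at -0.45, PSMC3 at -0.49 and PSMD1 at -0.35 against PSMD8 at 0.38 (camera adjusted p = 0.0001; adjusted p = 0.455 with an estimated correlation). Of 53 tested nuclear-encoded oxidative phosphorylation genes, 29 fell and 5 rose, with ATP5MC3 at -0.30, SDHD at -0.29, UQCRFS1 at -0.31 and ATP5F1A at -0.25. This list passed with camera adjusted p = 0.016, and did not pass without DTHIB replicate 2 (adjusted p = 0.0592), under quantile normalization (0.358, where 16 members rose), on recovered reads (0.18) or with an estimated correlation (adjusted p = 0.696). Counts adjusted over the list alone were identical in these 4 lists. The 13 mitochondrially encoded genes were listed at 0 in all libraries and could not be compared.

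**Figure D2:**
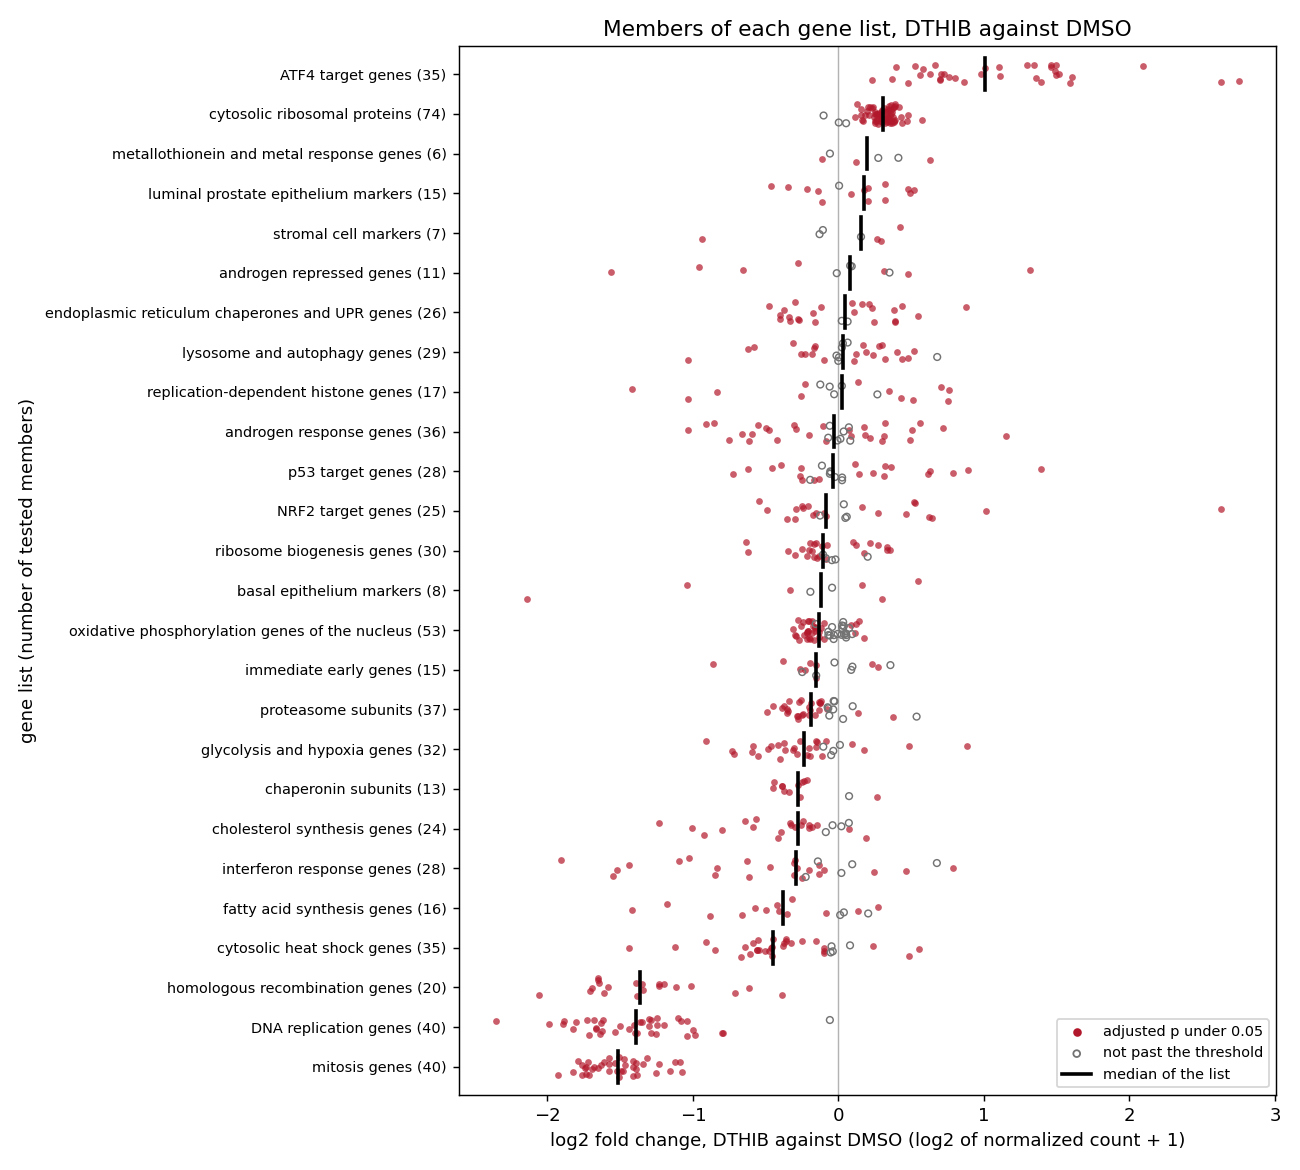
Log2 fold change, DTHIB against DMSO, of the tested members of 26 gene lists (horizontal axis); each point is a gene, filled where limma's adjusted p was under 0.05, and each bar is the median of its list. The mitosis, DNA replication and homologous recombination medians lie at -1.52, -1.39 and -1.37, and the ATF4 target median at 1.00.

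Interferon response genes were mostly lower, 20 of 28 tested, with 3 higher, by both adjustments. The antiviral enzyme OAS3 fell from 1024 ± 60.7 to 377 ± 22.6 normalized counts, IFITM1 from 123 ± 7.22 to 32.1 ± 2.45, PARP9 had a log2 fold change of -0.30, and the exonuclease ISG20 rose by 0.79. Camera gave adjusted p = 0.013, adjusted p = 0.283 with an estimated correlation, and 0.113 on recovered reads. NRF2 target genes were divided, 9 of 25 higher and 12 lower (camera adjusted p = 0.86): the ferritin chains FTH1 (0.64) and FTL (0.46) rose with SLC7A11, and glutathione reductase GSR fell (-0.55). SLC7A11 is also a member of the ATF4 list. Of 28 tested p53 targets, 11 rose and 9 fell (camera adjusted p = 0.64), with SESN2 at 1.39, GADD45A at 0.89, ZMAT3 at 0.79 and PPM1D at -0.62. Lysosome and autophagy genes had 12 of 29 members higher and 10 lower (camera adjusted p = 0.48), with the acid glucosidase GAA at 0.52, PSAP at 0.32, GLA at -1.03 and FNIP2 at -0.58. Counts adjusted over the list alone were identical for NRF2, p53 and lysosome genes. Of 15 tested immediate early genes, 2 rose and 7 fell, or 2 and 5 adjusted over the list alone (camera adjusted p = 0.67); NR4A1 (-0.38), JUNB (-0.23) and JUN (-0.20) fell and MYC rose (0.27). Among 6 metallothionein and metal response genes 2 rose and 1 fell by both adjustments (camera adjusted p = 0.51). MT1X rose by 0.63, while the calls of MT2A (0.12) and MTF1 (-0.11) were lost in several fits without 1 library, and MT1F (0.27) passed only without DMSO replicate 4 (adjusted p = 0.00586). Of 4 tested AHR targets, too few for a list test, CYP1A1 (-1.68), TIPARP (-0.52) and NQO1 (-0.18) fell, by both adjustments, and CYP1B1 had a log2 fold change of -0.15. The median and the mean log2 fold change differed in sign for the NRF2 (-0.09 and 0.15), p53 (-0.04 and 0.07), androgen-repressed (0.08 and -0.08), stromal (0.16 and -0.01) and histone lists (0.02 and -0.0032), and the basal list had both below 0 with a camera direction above. In some fits without 1 library the NRF2, androgen-repressed and histone medians changed sign. They were 0.02 without DMSO replicate 2, -0.02 without DMSO replicate 4 and -0.03 without DTHIB replicate 1, respectively.

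Luminal prostate epithelium markers had 9 of 15 members higher and 5 lower by both adjustments (camera adjusted p = 0.157); KLK3 and the prostate-specific membrane antigen FOLH1 (0.48) rose, and the keratin KRT8 (-0.35) fell. Of 8 tested basal epithelium markers, 3 rose and 3 fell, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.95), with LAMA3 at 0.55, ITGA6 at 0.30, LAMB3 at -1.04 and DST at -0.33. Of 7 tested stromal markers, 3 rose and 1 fell by both adjustments (camera adjusted p = 0.54): COL1A1 (0.42) and FN1 (0.29) rose, ACTA2 (-0.94) fell, and the rise of TAGLN (0.26) was lost in 6 of the 8 fits without 1 library. Of 19 neuroendocrine markers 4 could be tested, ENO2 (-0.46) and NCAM1 (-1.10) lower, SYP (0.42) and ONECUT2 (0.24) higher, by both adjustments. NCAM1 had a mean of only 12.5 normalized counts, near the limit of 10 for testing, and a deposited log2 fold change of -0.77. The ONECUT2 call was lost after removal of the trend with length and GC (0.10, adjusted p = 0.163). Of 18 blood cell markers 3 could be tested, all with mean normalized counts under 20 in each group. LYZ fell from 16 ± 1.6 to 4.34 ± 1.73, by both adjustments. CD68 (log2 fold change 1.04) and CSF1R (-0.58) did not pass, although CD68 did without DMSO replicate 1 (adjusted p = 0.0335). Over the fits without 1 library the log2 fold change of CD68 ranged from 0.35 to 1.40.

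The largest rises included DMGDH, a mitochondrial choline-pathway enzyme (chromosome 5, 78997606 to 79236038), with a log2 fold change of 2.95 (SE 0.13), from 32.2 ± 5.81 to 252 ± 14 normalized counts. CHAC1 (chromosome 15, 40952962 to 40956519) had 2.75, SLC7A11 (chromosome 4, 138164097 to 138242349) 2.63, the extracellular matrix protein RELN 2.58, COL16A1 2.46, SHC2 2.45 and the calcium-binding protein S100P 2.26. PDE2A (2.19), TBC1D10C (2.18), CTH (2.09), the pseudogene SSPOP (1.97) and the protease CAPN5 (1.97) complete the 12 largest. The intestinal chloride transporter SLC26A3 (chromosome 7, 107765467 to 107803225) fell most, with a log2 fold change of -4.66 (SE 0.11), from 734 ± 58.9 to 28.2 ± 4.78. RUNX1, a transcription factor, had -3.08, RRM2 -2.35, ACTL8 -2.21, the cohesin acetyltransferase ESCO2 -2.18, LRG1 -2.09, the kinase SGK1 -2.09, EXO1 -2.06, TMEM100 -2.05, NAV2 -2.05, the histone chaperone ASF1B -2.05 and the receptor S1PR3 -2.03.

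The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Strand was not stated in the counting, so genes that overlap a gene on the opposite strand are uncertain. With partners of at least 0.1 times their mean, these are DNAJB1 with TECR, HSF1 with DGAT1, ACAT2 with TCP1, CCNA2 with EXOSC9, ESCO2 with PBK and CCDC25, BRCA1 with NBR2, KRT8 with KRT18, TBC1D10C with PPP1CA, FADS1 with FADS2, FEN1 with TMEM258 and JUNB with HOOK2. So are PARP9 with DTX3L, SREBF1 with RAI1, CSF1R with RPL7P1, SDHD with TIMM8B, GNL3 with GLT8D1 and PBRM1, ACTA2 with FAS and STAMBPL1, TAGLN with PCSK7, ANLN with MATCAP2, CYP1B1 with RMDN2 and CD68 with a gene without a symbol. FEN1 with FADS2, IFITM1 with IFITM2, ENO2 with LRRC23, and BRCA1 and CD68 each with a gene without a symbol overlap on the same strand, which strand would not separate. Genes named only after their values were seen were not examined for overlaps. Families of near-identical genes and pseudogenes such as ribosomal proteins, histones and metallothioneins are uncertain too.

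The authors' deposited table, a DESeq2 result, held 10301 genes with an adjusted p under 0.05, 4863 higher and 5438 lower, of which 1040 had at least a 2-fold change. Of the calls in the authors' deposited table, 9864 were among the genes tested here and 9860 of these also changed by limma, all 9860 in the same direction. By limma 1250 further genes changed that were not calls in the deposited table, among them SYP and TAGLN (deposited DESeq2 adjusted p = 0.0547 and 0.0538). Deposited fold changes of low genes such as LYZ were smaller (-1.13 against -1.73 here), so the counts of 2-fold changes are not alike in measure.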

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

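No test in this part was chosen after the result was seen. Within each group of 4 libraries, a value was singled out when its gap to the nearest other library, divided by the group's whole range, exceeded Dixon's critical value, which chance does in about 1 of 20 groups; 15 of 286 groups met this, close to what chance gives. In the DMSO group, the normalized counts of replicate 2 were 468 for CTH against 526 to 535 in the other libraries, 987 for ERN1 against 972 to 974, 134 for IFITM1 against 119 to 120 and 2594 for JUN against 2469 to 2483. DMSO replicate 4 had 4596 for FEN1 against 4867 to 4902, 4286 for ANLN against 4639 to 4704, and a total of 29499458 reads against 30715400 to 30926053. In the DTHIB group, replicate 1 had 2166 normalized counts for CLU against 1878 to 1922 and 4481 for GAA against 4728 to 4755, and replicate 2 had 343 for OAS3 against 385 to 392. DTHIB replicate 3 had 570.3 for S1PR3 against 439.8 to 449.8, 1028 for E2F1 against 973 to 982, 1382 for SESN2 against 1487 to 1505, 12590 for SREBF1 against 10611 to 10848 and 17226 for FN1 against 19409 to 19672. The call and direction of each of these genes were the same in every fit without 1 library.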

How the results depend on the processing

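The fits without genes that have copies outside the primary assembly, with a length and GC trend removed, with thinned reads, and camera without a variance trend were chosen only after the data were seen. The number of changed genes ranged from 9483 to 11557 over the alternatives (10367 to 10893 without 1 library), the higher ones from 4258 to 5628 and the lower ones from 5164 to 5929. The number changed at least 2-fold was 2578 with no filter on low values, where more low genes are tested, and 701 with a mean of at least 50, where fewer are; it ranged from 1280 to 1465 without 1 library. Of the 141 named genes, 133 kept their call and none changed sign past a threshold. With an estimated inter-gene correlation the adjusted p was 0.283 for replication, mitosis, recombination, ribosomal protein and interferon genes, 0.33 for heat shock, 0.335 for cholesterol, 0.433 for chaperonin, fatty acid and glycolysis, 0.455 for proteasome and 0.696 for oxidative phosphorylation genes. With no variance trend as well it was 0.0605 for ATF4 targets, 0.324 for replication, recombination and interferon, 0.396 for heat shock, mitosis, cholesterol and ribosomal protein, 0.501 for chaperonin, fatty acid, glycolysis and proteasome, and 0.673 for oxidative phosphorylation genes. In the 12 lists that lost their call with the variance trend the estimates were 0.032 to 0.76, above the preset 0.01. A higher correlation widens the variance of a list's mean. With an estimated correlation camera also uses fewer degrees of freedom, and how much each contributed to the lost calls was not separated. The oxidative phosphorylation list (0.016) had 0.358 under quantile normalization, 0.18 with edgeR on recovered reads and 0.00783 to 0.0592 without 1 library, highest without DTHIB replicate 2; interferon genes had 0.113 with edgeR on recovered reads. For these the cause was not tested. Of 940 member counts compared, 35 moved by over 1.5 times, mostly counts of at most 2 genes. With the replicate number as a block 11058 genes changed; same-numbered libraries did not deviate together (correlations -0.0715 to 0.0144), and 1 of 8 correlated best with its own number, so the numbers were not taken to pair samples. Depth limits what can be said of genes under 10 normalized counts.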

Other observations

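The 6 additional lists, the test for gene copies outside the primary assembly, the exact test of list medians and the comparison of kinds of splits were chosen only after the results were seen; the ribosomal protein, cell cycle and synthetase patterns had also been seen before their tests were set. After their values were seen, the rules for depth and for the synthetases were made stricter, and the scaling tests were cut to quantile normalization. Counts by gene class were taken without a test of the difference between classes. Of 1131 tested antisense genes 449 rose and 126 fell, and of 894 lincRNA genes 340 rose and 114 fell, against 3835 and 5272 of 13162 protein-coding genes; without strand, antisense reads cannot be told from those of the opposite gene. MALAT1, a nuclear RNA, had a log2 fold change of 1.45 and NEAT1 of 0.92. Of 16 snoRNA host RNAs, 13 rose and none fell (median 0.58), with GAS5 at 0.94 and SNHG5 at 0.73 (camera adjusted p = 1.6e-06; adjusted p = 0.161 with an estimated correlation).

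Of 64 tested mitochondrial ribosomal proteins, 44 fell and 1 rose (median -0.16; camera adjusted p = 1.6e-06; adjusted p = 0.24 with an estimated correlation). Of 24 spliceosomal proteins, 22 fell and 1 rose (median -0.27; camera adjusted p = 1.5e-06; adjusted p = 0.161 with an estimated correlation), with SNRPA1 at -0.91 and SNRPB at -0.70. Of 20 cytosolic aminoacyl-tRNA synthetases 12 rose and 3 fell (camera adjusted p = 0.00051; adjusted p = 0.242 with an estimated correlation), and of 16 mitochondrial ones 2 rose and 12 fell (camera adjusted p = 0.0065; adjusted p = 0.24 with an estimated correlation). The medians were 0.40 and -0.23, a difference of 0.638 (permutation p = 0.00079 over genes, which are not independent replicates). Without the 4 cytosolic enzymes in the ATF4 list the cytosolic median was 0.09 and the difference 0.32 (permutation p = 0.025), most of it from the lower mitochondrial median, so a general rise of the cytosolic enzymes is not shown.

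Some abundant genes differed several-fold between replicates of one group: 39 of 11890 genes with a mean of at least 100 had a range above 1.5 on the log2 scale, such as PYCR3 with 805 normalized counts in DMSO replicate 2 and 13.5 to 31.1 in the other DMSO libraries. Libraries simulated with the replicate spread usual at each expression level, not each gene's own, gave 0 such genes. This argues against sampling noise at that level, but not against a larger spread of these genes themselves. No library held the farthest value in more than 23.1% of the 39, which argues against 1 poor library. Of the 39, 79.5% (31) have transcripts outside the primary assembly, against 2.04% of the other 11851 (odds ratio 184.9, Fisher's exact p = 1.4e-44), so reads placed on such copies in some libraries are a candidate explanation. The other 8 genes, NXF2, U2AF1, RGPD5, CSAG2, GATD3 and 3 without a symbol, have no such transcripts. Copies within the primary assembly were not examined, so these 8 genes do not speak for or against shared reads. Of the 39, 11 were called changed, RNH1, PARN and U2AF1 among them, and 212 of the 450 tested genes with such copies; no biological explanation was tested.

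The rise of cytosolic ribosomal protein transcripts was small, so scaling and composition were weighed. Relative to all genes the list median was 0.279 under quantile normalization. After removing the trend with length and GC the list median itself was 0.314, and that of all genes -0.0058. These values argue against both as the whole cause. TMM factors move all genes of a library alike and test nothing here. Of 14 tested translation factors with 5' terminal oligopyrimidine motifs, 11 rose and 2 fell, with a median of 0.253 (camera adjusted p = 0.00028; adjusted p = 0.24 with an estimated correlation). A shared change of such transcripts under DTHIB may therefore underlie the rise, as a hypothesis; RNA stability and synthesis were not measured.

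The 100 tested replication, mitosis and recombination genes (99 lower, median -1.47) were weighed against scaling and depth. Relative to all genes the median was -1.44 under quantile normalization, which argues against scaling that varies with expression level as the whole cause. A factor per library moves all genes alike and is not tested this way. Thinning to equal reads gave -1.444, but it could not have come out otherwise, since read totals differed by at most 0.18 on the log2 scale. That difference is itself far smaller than the median fall of these genes, which argues against depth as the whole cause. Fewer dividing cells under DTHIB may contribute to the fall, an untested hypothesis that cell cycle profiling or counts of cells would decide.

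Over the 35 splits of the 8 libraries into 4 and 4, 1 split, the real one, gave as many changed genes (11110 against at most 1 in any other), as many higher (5324 against 1), as many lower (5786 against 1) and as many changed at least 2-fold (1368 against 1). This gives an exact permutation p of 0.0286, the smallest the design allows, so chance is not excluded. Every other split mixes the groups, so the group difference adds to its spread and leaves few calls. The number of gene lists called, 13, did not stand out among the splits: 8 splits gave as many and the highest other gave 14. The 16 splits with 3 libraries of one group on a side, which keep part of the group difference, gave 9 to 14 lists, and the 18 with 2 and 2 gave 0 to 5. As a second look, the median of each list relative to all genes was compared over the same splits: it was largest in the real split for 20 of 26 lists, including all 13 called (exact permutation p = 0.0286, the smallest the design allows, adjusted p = 0.0371). That test asks whether a list's median differed between groups, not whether the list differed more than others.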
